A study of Mus musculus with 6 samples.

How the data were processed

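Liver RNA was measured in 6 wild-type C57BL/6 mice, 3 per group, and the labels name each animal by its own number, so the replicates are different mice. Replicates are numbered 1 to 3 in each group in the order of deposition only, and the numbers pair no animals across the groups. Per the labels, poly(A) RNA was made into libraries with a stranded mRNA kit, fragmented, reverse transcribed with random primers and sequenced from both ends.

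The authors deposited a gene table and a transcript table, each with an estimated count and an FPKM value per library. Per the submitters' processing notes, the tools were FastQC 0.11.7, HISAT2 2.1.0 and StringTie 1.3.4d with the mouse build mm10. The deposited counts are expected (estimated) counts and not tallies of whole reads. In each library they equalled the deposited FPKM times the transcript length times 1 constant for that library, so they carry the assembler's coverage estimates and its division of reads among isoforms and near-identical copies. The deposited FPKM values were rescaled here to TPM by dividing each by its library's sum. How strand was set in counting, and the annotation release, are not given in the sources used here, so antisense and overlapping genes are uncertain. No column of the tables was left unused for lack of a matching sample. Coordinates are those of the authors' transcript table on mm10, counted as printed there.

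Total estimated counts ran from 58422095 to 72431373 per library. Estimated counts do not have the sampling error of read counts, so the replicate spread sets the precision here and any floor covers counting error only.

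Groups were compared in R 4.3.3 with edgeR 4.0.16 on the deposited counts, which were already whole numbers. Genes were kept by filterByExpr with the group as its design, libraries were scaled by TMM, dispersions were estimated robustly, and rhCYGB was compared with vehicle by the quasi-likelihood F test with Benjamini-Hochberg adjustment over the 14415 genes kept. The threshold was an adjusted p of 0.05. The same test was run on 19664 transcripts. CPM values are counts scaled to the TMM-adjusted library total, fold changes are log2 of rhCYGB over vehicle, and SE is the size of the log2 fold change over the square root of its F. A set of 41 gene lists was tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with a correlation estimated per list, and with fry. Adjusted p-values of lists are over all 41 lists.

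The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes Cygb in each library and the genes past the threshold with the largest changes. With fewer than 10 past it, the rule takes the 10 smallest p-values, reported as not past the threshold. Predicted genes and pseudogenes are left unnamed. From each list it takes the members past the threshold, filled up to 2 with the members of highest mean CPM. For transcripts it takes those past the threshold whose gene was not. Genes named outside the rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

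The gene test was tested on simulated data drawn from these libraries' means and dispersions with 200 genes changed. For this comparison it recovered 0% of 2-fold changes, 28.5% of 4-fold changes and 87% of 8-fold changes among 14233, 14241 and 14238 genes. Of its 1, 60 and 186 calls in these settings, 1, 3 and 12 were false. It called 0 genes when nothing was changed. Each gene was drawn independently, so the simulation lacks differences between libraries that many genes share.

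Alternatives planned in advance were DESeq2 1.42.0 size factors, upper-quartile factors, no expression filter, at least 1 CPM in 3 samples, the DESeq2 test, limma-voom with sample quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), an adjusted p of 0.1, and leaving out each library in turn. Alternatives chosen after seeing the data removed each library's loess trend on transcript length, with or without GC content, used the length slope as a covariate, dropped the voom weights, used glmQLFit with legacy=FALSE, used the default DESeq2 filtering target of 0.1, left out Rn45s or both rhCYGB replicates 2 and 3, or removed the length trend under an estimated list correlation.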

Results

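The study asks how injected recombinant human cytoglobin (rhCYGB) affects gene expression in the injured mouse liver. Cytoglobin is an oxygen-binding globin that is found in hepatic stellate cells. All 6 mice ate a diet with 0.1% DDC (3,5-diethoxycarbonyl-1,4-dihydrocollidine), a compound that blocks heme synthesis and causes bile duct injury and scarring, for 4 weeks. During the second part of that time, 2 weeks long, 3 mice received rhCYGB at 2 mg/kg, 2 times a week, and 3 received saline vehicle, and livers were taken 2 days after the last dose. Liver mRNA was sequenced from each mouse. Values below are mean ± SD over n = 3 mice per group, with vehicle first and rhCYGB second.

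Total estimated counts were 58422095, 66174274 and 59629274 in vehicle replicates 1 to 3 and 65305340, 72431373 and 59739026 in rhCYGB replicates 1 to 3. Genes with a count numbered 16290, 16040 and 15992 with vehicle and 16060, 15542 and 14933 with rhCYGB. The libraries did not part cleanly by group. The first principal component of log2 CPM held 67.6% of the variance and placed rhCYGB replicate 1 at -52.7, among the vehicle libraries at -81.3, -24.5 and -32.9, while rhCYGB replicates 2 and 3 lay at 61.6 and 129.8. Pearson correlations of rhCYGB replicate 1 were 0.970, 0.965 and 0.974 with the vehicle libraries and 0.915 and 0.878 with the other rhCYGB libraries. Libraries also differed by transcript length. Per doubling of length, log2 expression deviated from the 6-library mean by 0.40, -0.02 and 0.06 in vehicle replicates 1 to 3 and by 0.24, -0.35 and -0.33 in rhCYGB replicates 1 to 3. The share of counts on the ribosomal RNA gene Rn45s was 0.319%, 0.326% and 0.225% with vehicle and 0.321%, 0.443% and 1.74% with rhCYGB.

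**Figure D1:**
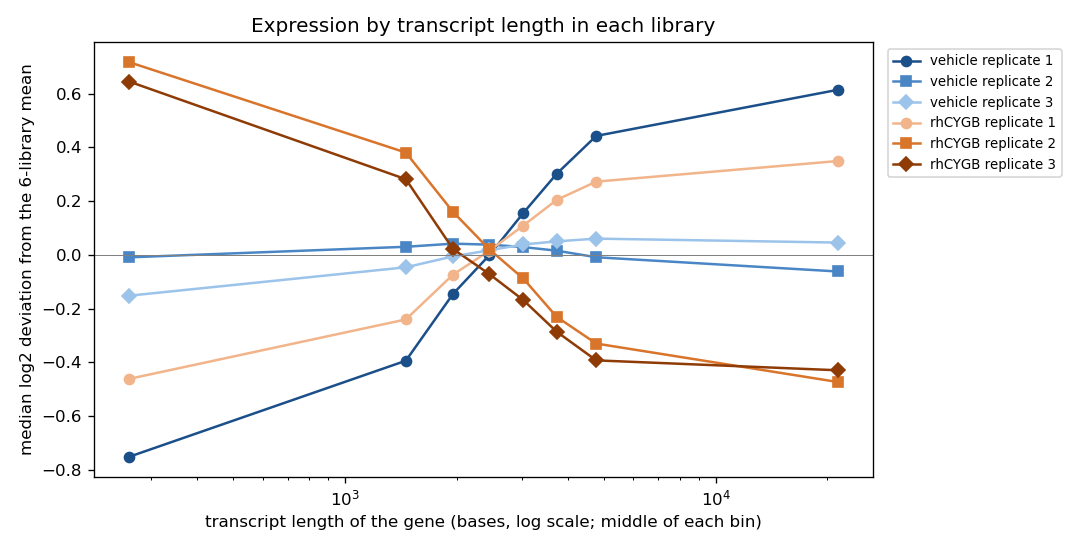
Median log2 deviation from the 6-library mean in each library (lines) for 8 bins of genes ordered by transcript length (x axis, bases, log scale). rhCYGB replicates 2 and 3 were highest for the shortest genes, at 0.72 and 0.64, where vehicle replicate 1 was at -0.75 and rhCYGB replicate 1 at -0.46.

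With rhCYGB, lists of plasma protein, acute phase, detoxification, bile acid and heme genes tended to have higher values. Lists of matrix, cytokine, monocyte, antigen presentation, interferon, cell division, cholesterol synthesis and fat synthesis genes tended to have lower ones. Single libraries set some of these differences. The cell cycle median was -2.58 in rhCYGB replicate 3 and between 0.15 and 0.92 in the others. Both lipid synthesis lists were highest in rhCYGB replicate 1 and lowest in rhCYGB replicate 3. By camera with an estimated correlation 0 of 41 lists passed (smallest adjusted p = 0.421). By edgeR 0 single genes passed and 1170 had an unadjusted p under 0.05, while DESeq2 called 62 and limma-voom with sample quality weights 4410. Among the genes with the smallest p-values were Alas1, which makes the first enzyme of heme synthesis, at 176 ± 11.0 and 587 ± 184 CPM, and Gpx2, a glutathione peroxidase, at 5.16 ± 1.15 and 21.0 ± 4.14 CPM. Mouse Cygb itself (gene 114886, chromosome 11, 116645595 to 116654313) was at 31.3, 29.9 and 22.2 CPM with vehicle and 19.4, 14.8 and 6.64 CPM with rhCYGB, a log2 fold change of -1.03 (SE 0.41, edgeR unadjusted p = 0.0380, adjusted p = 0.523). The injected agent is a protein and adds no transcript, so this gene does not check the labels.

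By edgeR, 0 of 14415 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.523. At an unadjusted p under 0.05 there were 1170 genes, 873 higher and 297 lower with rhCYGB. With 1 library left out that count ran from 298, without vehicle replicate 1, to 6152, without rhCYGB replicate 1. The share of higher genes at that p depended on scaling, on the test and on single libraries. It was 74.6% by edgeR with TMM, 52.0% with upper-quartile factors and 49.4% by limma-voom without weights. The medians of all genes were then -0.06, -0.18 and -0.08. By edgeR with TMM the share was 49.4% without rhCYGB replicate 1, 49.9% without rhCYGB replicate 3 and 56.7% without vehicle replicate 1. Without any other library it lay between 61.6% and 68.7%, and with the length slope as covariate it was 49.1%. By limma on log2(TPM + 1), where scaling, filter and test all differ, it was 8.44%, with a median of -0.61. DESeq2 called 62 genes (60 higher, 2 lower) among the 1890 left by its own filtering. Among the genes named here these included Alas1 (DESeq2 adjusted p = 1.64e-04), Cyp2a5 (0.00106), Cyp4a14 (1.77e-04), Gstm1 (0.0200) and Asl (0.00332), all higher with rhCYGB. The ribosomal RNA gene Rn45s was called higher as well (DESeq2 adjusted p = 0.0423). Its default filtering target, tried after the results were seen, gave 48 of 17475 (41 higher, 7 lower). Limma-voom with sample quality weights called 4410 (2362 higher, 2048 lower), limma-voom without weights 0, and limma on log2(TPM + 1) 0. Those weights, estimated from the same data, were 0.173, 2.60 and 0.473 in rhCYGB replicates 1 to 3. With rhCYGB replicate 1 left out edgeR called 3391 genes (1854 higher, 1537 lower), and leaving out any other single library gave 0. CPM of the groups did not overlap for 1932 genes, 13.4% of those tested, where chance gives 10%. With at least a 2-fold change 0 genes passed by edgeR, 62 by DESeq2 and 2315 by quality-weighted limma-voom, and 896 genes had an unadjusted p under 0.05 with such a change.

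The 10 genes with the smallest p-values, none past the threshold (edgeR adjusted p = 0.523 for each), are described next. Alas1 (chromosome 9, 106233455 to 106247954) had a log2 fold change of 1.73 (SE 0.33) and Gpx2 (chromosome 12, 76792335 to 76795554) of 2.03 (SE 0.30). Socs2 (chromosome 10, 95411490 to 95416857), a feedback inhibitor of growth hormone signalling, was at 18.8 ± 4.39 and 61.1 ± 25.8 CPM. The antimicrobial peptide gene Defb1 (chromosome 8, 21776555 to 21795185) was at 7.23 ± 1.64 and 17.5 ± 0.266 CPM. Ppp1r3g, a glycogen-targeting phosphatase subunit, was at 0.193 ± 0.130 and 10.3 ± 9.05 CPM, and the protease inhibitor gene Timp4 was at 0.0554 ± 0.0509 and 4.82 ± 6.47 CPM, with 12.3 CPM in rhCYGB replicate 3 alone. Xcr1, a chemokine receptor of cross-presenting dendritic cells, was at 0.601 ± 0.0761 and 0.0899 ± 0.0328 CPM. Mgl2, a lectin of macrophages and dendritic cells, had 51, 28 and 15 estimated counts with vehicle and 0 in all 3 rhCYGB libraries, at least 23.4-fold lower against a floor of 3 counts over the group. Fhdc1 was at 0.752 ± 0.267 and 0.0949 ± 0.0179 CPM. Pcdhgb6, at 1.78 ± 0.434 and 0.0261 ± 0.0451 CPM, shares exons with other genes of its protocadherin cluster, so its value is uncertain.

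**Figure D2:**
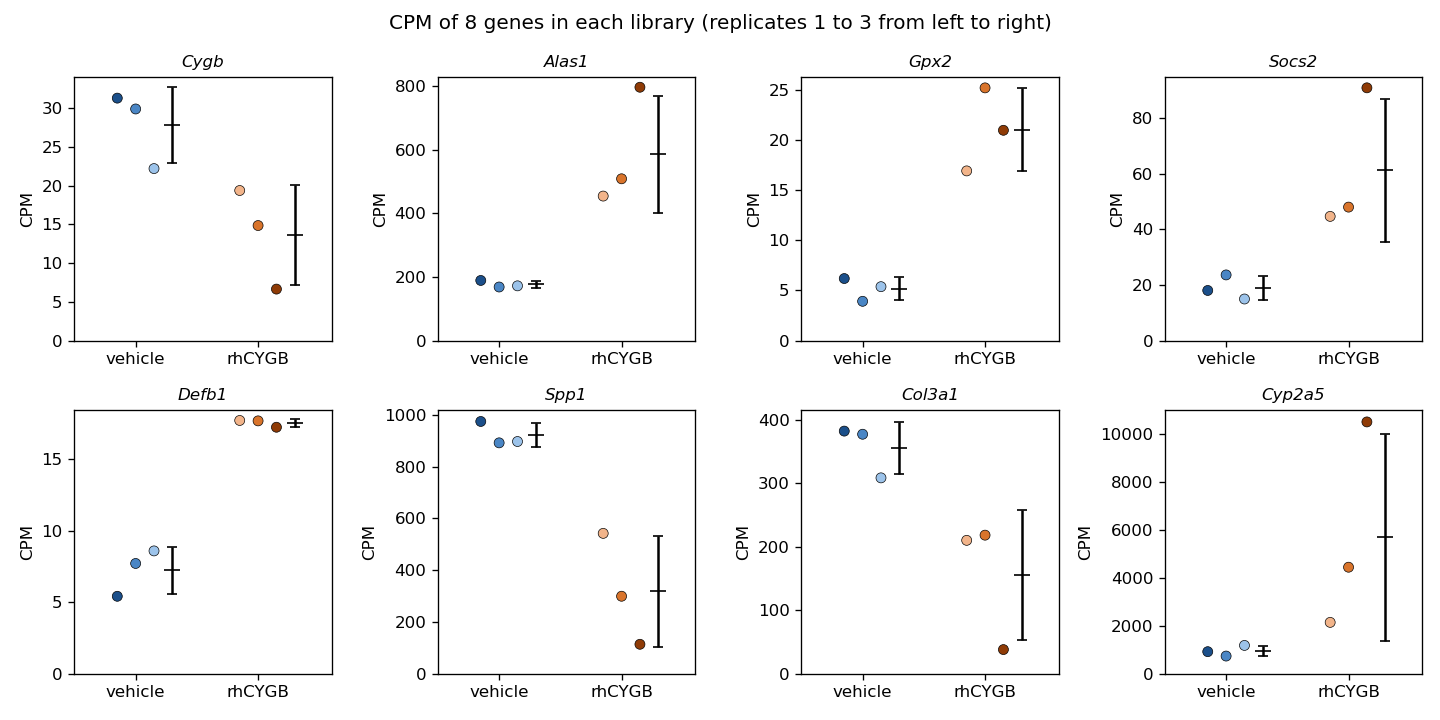
CPM (y axis, from 0) of 8 genes in each library (points, replicates 1 to 3 from left to right in each group), with the group mean and SD (bars). Alas1 lay between 168 and 189 CPM with vehicle and between 454 and 797 CPM with rhCYGB, and Cygb between 22.2 and 31.3 against 6.64 to 19.4 CPM.

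Of the 41 gene lists, 22 passed camera with the preset correlation, 11 higher and 11 lower with rhCYGB, and 0 passed with an estimated correlation (smallest adjusted p = 0.421) or with fry in either form. No list member passed by edgeR when adjusted over all genes, while DESeq2 called some, among them those given above. Some of the 22 calls were also lost with the preset correlation when a setting changed. The cholesterol synthesis and the fatty acid and triglyceride synthesis lists did not pass on log2(TPM + 1) (adjusted p = 0.0504 and 0.0619), without vehicle replicate 2 (0.0818 and 0.0545) or without rhCYGB replicate 3 (0.336 and 0.204), nor the pericentral list without vehicle replicate 2 (0.0580). Without rhCYGB replicate 1 the matrix protease (0.149), monocyte (0.0650), NRF2 (0.0693) and MHC class II (0.0650) lists did not pass. Because the list calls were lost with an estimated correlation, the lists below are described by their values.

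Hepatocyte genes made up most of the lists with higher values. In the list of plasma proteins and liver nuclear factors 26 of 28 members were higher, with a median log2 fold change of 0.80 (camera with the preset correlation, adjusted p = 6.49e-06, and adjusted p = 0.504 with an estimated correlation). Its most abundant members were Alb at 63542 ± 15808 and 117969 ± 39949 CPM and Trf at 34986 ± 9446 and 39858 ± 9407 CPM. Much of the Alb difference came with the scaling. Its unscaled share of counts was 6.66%, 8.18% and 7.97% with vehicle and 8.44%, 10.5% and 8.86% with rhCYGB. The TMM factors, by which all CPM here are divided, were 1.45, 1.07 and 1.18 with vehicle and 1.18, 0.74 and 0.63 with rhCYGB. Of the cytochrome P450 and conjugation genes, which clear drugs and toxins, 30 of 35 were higher, median 0.65 (camera with the preset correlation, adjusted p = 1.10e-07, and adjusted p = 0.421 with an estimated correlation), and 13 had an unadjusted p under 0.05, all higher. Cyp2a5 at 940.3 ± 224 and 5702 ± 4330.2 CPM and Cyp3a11 at 5070.3 ± 1479.9 and 5786 ± 1761 CPM were the most abundant. Periportal genes were higher in 20 of 22 members, median 0.61 (camera with the preset correlation, adjusted p = 6.40e-05, and adjusted p = 0.432 with an estimated correlation), with Cps1 at 2631 ± 417 and 4045 ± 1401 CPM, the first enzyme of the urea cycle. Pericentral genes were higher in 15 of 20, median 0.54 (camera with the preset correlation, adjusted p = 0.0244, and adjusted p = 0.492 with an estimated correlation), with Gstm3 at 1965 ± 597 and 3497 ± 1462 CPM. The medians of these 4 lists with the length trend removed were 0.57, 0.63, 0.73 and 0.29. The pericentral list no longer passed then, at an adjusted p of 0.0582 by camera. The counts of higher members in these lists rest on the TMM scaling. With upper-quartile factors the medians of the 4 lists were 0.65, 0.51, 0.47 and 0.40. On log2(TPM + 1), where the median of all genes was -0.61, Trf, Cyp3a11 and Cps1 changed sign, while Alb, Cyp2a5 and Gstm3 did not. For the plasma protein list the library medians were -0.67, 0.0049 and -0.27 with vehicle and -0.36, 0.46 and 0.92 with rhCYGB, so rhCYGB replicate 1 sat with the vehicle libraries.

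Bile acid, heme and antioxidant genes were higher as well. Bile acid synthesis and transport genes were higher in 23 of 29 members, median 0.44 (camera with the preset correlation, adjusted p = 1.64e-04, and adjusted p = 0.421 with an estimated correlation), with Cyp27a1 at 285 ± 94.2 and 823 ± 571 CPM and Akr1c6 at 545 ± 133 and 652 ± 247 CPM. Genes listed for heme synthesis, which DDC blocks, and heme breakdown were higher in 15 of 19, median 0.45 (camera with the preset correlation, adjusted p = 0.00126, and adjusted p = 0.432 with an estimated correlation). Alas1 was the 1 member past 0.05 adjusted over the list alone (edgeR adjusted p = 0.0203), against 0 adjusted over all genes. The list as fixed in advance also held Hrg at 623 ± 101 and 2787 ± 2922 CPM, with an SD above its mean. Whether Hrg reports on heme synthesis was not tested. NRF2 targets and antioxidant enzymes were higher in 21 of 30, median 0.48 (camera with the preset correlation, adjusted p = 3.36e-04, and adjusted p = 0.432 with an estimated correlation), with Gstm1 at 3789.8 ± 1067 and 9764 ± 2689 CPM, a glutathione transferase. Acute phase proteins were higher in 24 of 30, median 0.53 (camera with the preset correlation, adjusted p = 0.00126, and adjusted p = 0.615 with an estimated correlation), with Hp at 9807 ± 4378 and 15334 ± 7975 CPM and Hpx at 12321 ± 4031 and 15642 ± 5800.3 CPM. With the length trend removed the medians of these 4 lists were 0.58, 0.34, 0.34 and 0.49.

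Fatty acid oxidation genes and other targets of the nuclear receptor PPAR-alpha were higher in 20 of 27 members, median 0.60 (camera with the preset correlation, adjusted p = 9.02e-06, and adjusted p = 0.421 with an estimated correlation). Adjusted over the list alone 3 passed, against 0 over all genes, and these were Cyp4a10, Cyp4a14 and Angptl4, each with edgeR adjusted p = 0.0466. Cyp4a10 and Angptl4 were chosen after their values were seen. Cyp4a14 was at 62.2 ± 27.8 and 522 ± 397 CPM. Female-biased liver genes were higher in 15 of 21, median 1.37 (camera with the preset correlation, adjusted p = 8.94e-05, and adjusted p = 0.421 with an estimated correlation), and 10 passed by edgeR adjusted over the list alone (9 higher, 1 lower) against 0 over all genes. These 2 lists share Cyp4a10, Cyp4a14 and Acot3, of which Acot3 was chosen after its value was seen. Male-biased genes did not pass (adjusted p = 0.443 by camera), with a median of -0.29 although camera gave the opposite direction, and with Gstp1 at 673 ± 238 and 1704 ± 714 CPM and Mup20 at 1233 ± 1047 and 1027 ± 363 CPM. All 6 libraries expressed 4 Y-linked genes above 1 CPM. With the length trend removed the PPAR-alpha and female-biased medians were 0.47 and 1.26. The small adipose, muscle and gut list, with 5 measured members, was higher in 4 of 5, median 1.46 (camera with the preset correlation, adjusted p = 0.0131, and adjusted p = 0.432 with an estimated correlation). The median of this list was 0.78 with the length trend removed. Adjusted over the list alone 2 of its members passed by edgeR, against 0 over all genes. Named for their abundance only, Fabp2 was at 36.7 ± 19.0 and 77.3 ± 44.2 CPM and Lgals4 at 5.04 ± 1.75 and 22.1 ± 14.7 CPM.

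**Figure D3:**
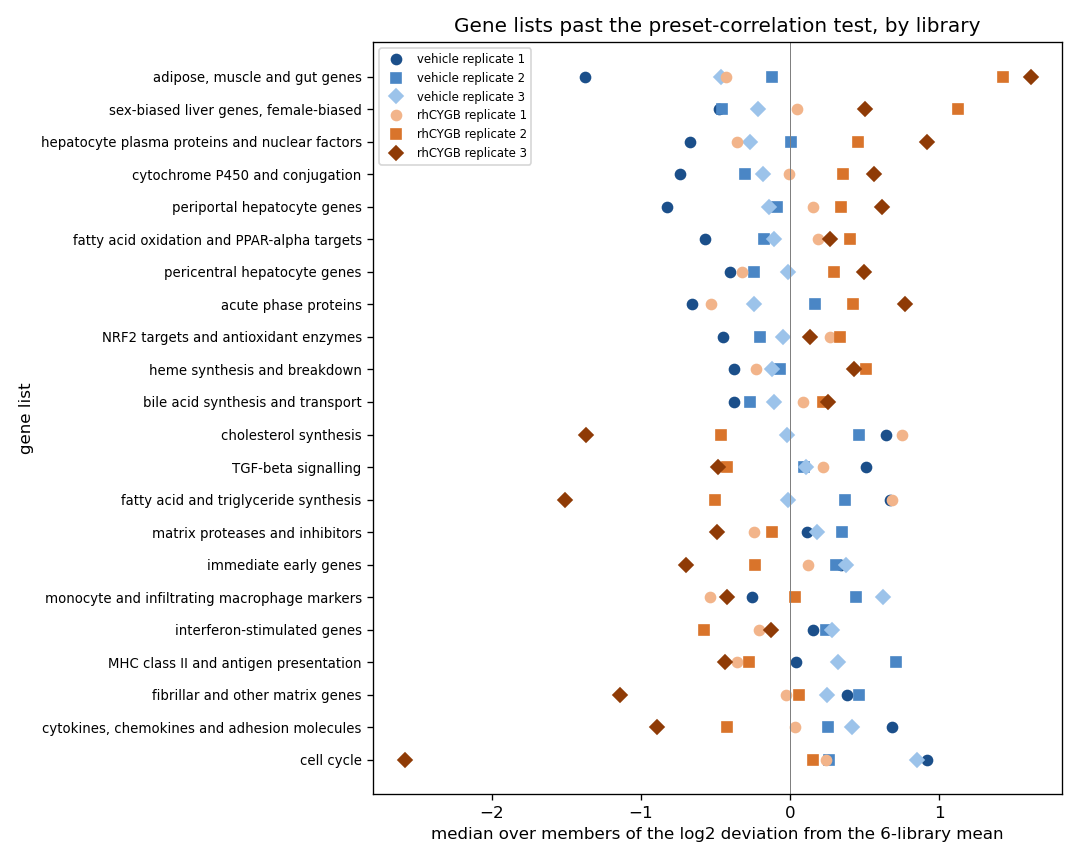
Median log2 deviation from the 6-library mean over the members of each of the 22 gene lists past camera with the preset correlation (rows), in each library (points). The cell cycle median was -2.58 in rhCYGB replicate 3 and between 0.15 and 0.92 in the other libraries.

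Matrix gene lists had lower values with rhCYGB. Fibrillar and other matrix genes were lower in 28 of 34 members, median -0.72 (camera with the preset correlation, adjusted p = 6.49e-06, and adjusted p = 0.504 with an estimated correlation), and their groups did not overlap for 18 of 34. Col3a1 at 356 ± 41.2 and 155 ± 102 CPM and Fn1 at 798 ± 56.1 and 662 ± 108 CPM were the most abundant. Library medians of this list were -0.024, 0.058 and -1.14 with rhCYGB, and its members are long, with a median length of 5441.5 bases. With the length trend removed its median was -0.50, and Fn1 then had a log2 fold change of 0.06 in place of -0.27. TGF-beta signalling genes were lower in 21 of 23, median -0.48 (camera with the preset correlation, adjusted p = 2.69e-04, and adjusted p = 0.522 with an estimated correlation), with Tgfbr2 at 78.0 ± 11.6 and 69.9 ± 14.6 CPM and Eng at 52.6 ± 5.53 and 52.1 ± 12.2 CPM, and a median of -0.34 with the length trend removed. Matrix proteases and inhibitors were lower in 17 of 24, median -0.53 (camera with the preset correlation, adjusted p = 0.00381, and adjusted p = 0.421 with an estimated correlation), with Ctss at 363 ± 132 and 215 ± 37.5 CPM and Mmp14 at 112 ± 37.4 and 177 ± 84.8 CPM. Timp4, which had higher values, was the 1 member past 0.05 adjusted over the list alone (edgeR adjusted p = 0.0485), against 0 over all genes. Markers of activated stellate cells, the main scar-forming cells of the liver, did not pass (adjusted p = 0.137 by camera), with a median of -0.20 and with Vim at 162 ± 65.7 and 141 ± 66.3 CPM and Cald1 at 241 ± 50.5 and 267 ± 29.0 CPM. The activated list passed, lower, with the length trend removed (camera adjusted p = 0.0124, median -0.34), when 0 of 41 lists passed with an estimated correlation, and without rhCYGB replicate 2 (1.35e-04). Quiescent stellate cell markers did not pass (adjusted p = 0.282), median -0.42, or -0.097 with the length trend removed, with Ecm1 at 68.0 ± 1.91 and 113 ± 44.9 CPM.

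Cytokine, monocyte, antigen presentation and interferon lists had lower values too, while acute phase proteins, described above, were higher. Cytokines, chemokines and adhesion molecules were lower in 27 of 31 members, median -0.83 (camera with the preset correlation, adjusted p = 7.57e-06, and adjusted p = 0.432 with an estimated correlation), with Ccl9 at 258 ± 95.4 and 247 ± 117 CPM and Cxcl12 at 167 ± 27.6 and 118 ± 55.8 CPM. Monocyte and infiltrating macrophage markers were lower in 18 of 21, median -0.56 (camera with the preset correlation, adjusted p = 2.41e-04, and adjusted p = 0.432 with an estimated correlation), with Lyz2 at 985 ± 352 and 772 ± 315 CPM and Gpnmb at 339 ± 222 and 176 ± 26.8 CPM. MHC class II and antigen presentation genes were lower in 18 of 19, median -0.64 (camera with the preset correlation, adjusted p = 2.43e-04, and adjusted p = 0.421 with an estimated correlation), with Cd74 at 185 ± 65.3 and 167 ± 139.7 CPM and H2-Aa at 77.7 ± 28.3 and 56.9 ± 38.5 CPM. Xcr1 was the 1 member of that list past 0.05 adjusted over the list alone (edgeR adjusted p = 0.0389), against 0 over all genes. Interferon-stimulated genes were lower in 22 of 29, median -0.57 (camera with the preset correlation, adjusted p = 8.98e-04, and adjusted p = 0.432 with an estimated correlation), although the most abundant members were higher, with Bst2 at 137 ± 46.2 and 189 ± 59.9 CPM and Irf7 at 44.9 ± 2.65 and 80.1 ± 31.2 CPM. With the length trend removed the medians of these 4 lists were -1.05, -0.70, -0.74 and -0.51.

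Cell cycle genes were lower in 33 of 35 members, median -0.97 (camera with the preset correlation, adjusted p = 4.14e-07, and adjusted p = 0.552 with an estimated correlation), with Ccnd1 at 187 ± 78.4 and 150.0 ± 58.1 CPM and Pcna at 70.3 ± 29.9 and 36.5 ± 14.9 CPM. Their medians were 0.92, 0.26 and 0.85 in the vehicle libraries and 0.24, 0.15 and -2.58 in the rhCYGB libraries, so rhCYGB replicate 3 set the size of the difference, and 0 of 35 members had an unadjusted p under 0.05. Cholesterol synthesis genes were lower in 20 of 25, median -0.46 (camera with the preset correlation, adjusted p = 0.00802, and adjusted p = 0.632 with an estimated correlation), with Fdps at 594 ± 181 and 573 ± 83.8 CPM. Fatty acid and triglyceride synthesis genes were lower in 20 of 25, median -0.52 (camera with the preset correlation, adjusted p = 0.0139, and adjusted p = 0.615 with an estimated correlation), with Fasn at 659 ± 280.0 and 339 ± 271 CPM and Scd1 at 8566 ± 1991 and 5301 ± 6336 CPM. Both lipid lists were highest in rhCYGB replicate 1, at 0.75 and 0.69, and lowest in rhCYGB replicate 3, at -1.37 and -1.51. Immediate early genes were lower in 20 of 25, median -0.53 (camera with the preset correlation, adjusted p = 0.00381, and adjusted p = 0.504 with an estimated correlation), with Jund at 121 ± 44.5 and 155 ± 60.2 CPM and Rhob at 56.9 ± 6.75 and 44.8 ± 11.2 CPM. With the length trend removed the medians of these 4 lists were -0.88, -0.43, -0.42 and -0.48.

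The other cell type lists did not pass camera with the preset correlation in the 6-library comparison, but some did under alternatives that keep at least 2 libraries per group, though none of them with an estimated correlation in that comparison. These were neutrophil markers, lower with the length trend removed, T and NK cell markers, higher on log2(TPM + 1) (adjusted p = 0.00866), and Kupffer cell markers, higher without rhCYGB replicate 3 (0.00655). Cholangiocyte markers passed, lower, on leaving out vehicle replicate 2 (0.0347), vehicle replicate 3 (0.0369), rhCYGB replicate 2 (0.0474) or rhCYGB replicate 3 (0.0231). With an estimated correlation in the 6-library comparison none of these 4 lists passed (adjusted p = 0.615, 0.874, 0.713 and 0.615 in the order named), and 0 of 41 lists did with the length trend also removed. Cholangiocyte and ductular markers, which mark the bile duct reaction to DDC, had a median of -0.28 (adjusted p = 0.101), with Spp1 at 921 ± 46.3 and 318 ± 215 CPM and Clu at 3745 ± 1466 and 3557 ± 864 CPM. Kupffer cell markers had a median of 0.055 (adjusted p = 0.320), which was -0.06 with upper-quartile factors, with C1qa at 239.8 ± 76.8 and 316 ± 146 CPM and C1qb at 258 ± 82.8 and 331 ± 144 CPM. Neutrophil markers had a median of -0.20 (adjusted p = 0.341), which was -0.59 with the length trend removed (camera adjusted p = 0.0281), with Lcn2 at 1265 ± 555 and 1217 ± 541 CPM and S100a9 at 23.3 ± 9.29 and 18.0 ± 4.44 CPM. Lcn2 was also in the acute phase and iron handling lists, so it does not stand for neutrophils alone. The cell source of each marker in whole-liver RNA was not tested. T and NK cell markers had a median of -0.048 (adjusted p = 0.676) while camera's direction was up, with Ccl5 at 2.01 ± 1.26 and 7.13 ± 2.91 CPM and Gzma at 0.980 ± 0.782 and 3.16 ± 0.599 CPM. B and plasma cell markers had a median of -0.27 (adjusted p = 0.644) and a mean of 0.031, with Sdc1 at 427 ± 52.0 and 355 ± 129 CPM and Cd22 at 3.28 ± 0.628 and 2.42 ± 0.902 CPM. Sinusoidal endothelial markers had a median of -0.19 (adjusted p = 0.370), with Plvap at 60.3 ± 5.77 and 72.9 ± 24.9 CPM and Stab1 at 62.1 ± 3.25 and 68.7 ± 14.3 CPM. Mesothelial and portal fibroblast genes had a median of 0.079 (adjusted p = 0.947), -0.05 with upper-quartile factors, with Gas6 at 107 ± 21.3 and 81.8 ± 16.2 CPM and Krt19 at 20.7 ± 1.65 and 31.7 ± 15.9 CPM. Pancreas genes had 3 measured members and a median of 0.48 (adjusted p = 0.404), which was -0.013 with the length trend removed, with Cela1 at 7.41 ± 2.60 and 8.96 ± 3.07 CPM and Cela2a at 0.375 ± 0.280 and 0.528 ± 0.289 CPM. Red blood cell genes had a median of -0.18 (adjusted p = 0.711). The near-identical globin genes Hba-a1 and Hba-a2 traded counts between libraries, with Hba-a2 at 0.0912 CPM and Hba-a1 at 136 CPM in rhCYGB replicate 1, so each alone is uncertain. Their sum was 111, 438 and 199.6 CPM with vehicle and 136, 505 and 282.5 CPM with rhCYGB, and Hbb-bs ranged from 2.43 to 497 CPM among vehicle libraries. Hba-a1 was chosen after its values were seen.

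The remaining stress and metabolic lists did not pass camera with the preset correlation in the 6-library comparison either, and 2 did under such alternatives, though not with an estimated correlation in that comparison. The unfolded protein list passed, lower, with the length trend removed (adjusted p = 0.0466, median -0.39), with at least 1 CPM in 3 samples (0.0441) and without vehicle replicate 3 (0.0118), rhCYGB replicate 2 (0.0474) or rhCYGB replicate 3 (0.0316). The circadian clock list passed, higher, with the length trend removed (0.0447, median 0.28) and without vehicle replicate 1 (0.0229) or rhCYGB replicate 2 (0.0474). Neither passed with an estimated correlation in the 6-library comparison (adjusted p = 0.552 and 0.614), nor with the length trend also removed. Iron handling genes had a median of 0.16 (adjusted p = 0.108). Hypoxia-responsive genes had a median of -0.27 (adjusted p = 0.287), with Eno1 at 671 ± 137 and 1178 ± 519.6 CPM and Ldha at 754 ± 204 and 649 ± 236 CPM. Circadian clock genes had a median of 0.098 (adjusted p = 0.238), -0.03 with upper-quartile factors, with Dbp at 56.1 ± 19.3 and 100.1 ± 41.4 CPM and Tef at 70.2 ± 18.9 and 93.8 ± 8.68 CPM. Unfolded protein and integrated stress response genes had a median of -0.46 (adjusted p = 0.0554), with Hspa5 at 822 ± 254 and 454 ± 157 CPM, a chaperone of the endoplasmic reticulum, and Calr at 976 ± 210.0 and 975 ± 353 CPM. The p53, senescence and cell death list had a median of -0.13 (adjusted p = 0.341), with Mcl1 at 141 ± 5.07 and 163 ± 23.8 CPM and Ccng1 at 54.6 ± 7.82 and 50.0 ± 16.5 CPM. Keratins and Mallory-Denk body genes, the protein aggregates that DDC induces, had a median of 0.32 (adjusted p = 0.388), with Krt8 at 1689.7 ± 199 and 1454 ± 422 CPM and Hspa8 at 1234 ± 231 and 1539 ± 589 CPM. With the length trend removed the median of that list was 0.0070 and camera's direction was down. The nitric oxide, arginine and globin list had a median of 0.21 (adjusted p = 0.416), with Asl at 276 ± 74.3 and 2734 ± 3050.4 CPM and Arg1 at 1179 ± 242 and 2424 ± 699.7 CPM, which act in the urea cycle.

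Transcripts gave the same count as genes. By edgeR 0 of 19664 transcripts passed, the smallest adjusted p was 0.456, and 795 had an unadjusted p under 0.05 (561 higher, 234 lower). Limma on log2(TPM + 1) called 1, a Jund isoform, chosen here after its value was seen, and edgeR without rhCYGB replicate 1 called 958, with the balance turned (256 higher, 702 lower). Division of counts among isoforms of 1 gene is uncertain in these tables.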

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

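Tests chosen after the results were seen are those with the length or GC trend removed, the length covariate, legacy=FALSE, voom without weights, rhCYGB replicates 2 and 3 both left out, Rn45s left out, the default DESeq2 filtering target and upper-quartile factors for lists and named genes. The edgeR count of 0 genes was also 0 with both other scalings, both other filters, an adjusted p of 0.1, the length, GC and covariate corrections, legacy=FALSE and Rn45s left out, and limma gave 0 on each TPM scale and by voom without weights. DESeq2 called 62 genes, all at least 2-fold, and 48 with its default filtering target of 0.1, again all at least 2-fold. Limma-voom with quality weights called 4410, of them 2315 at least 2-fold. Its weights were estimated from these same data. They were 0.457, 2.35 and 4.38 in vehicle replicates 1 to 3 and 0.173, 2.60 and 0.473 in rhCYGB replicates 1 to 3. Most of the rhCYGB weight thus lay on rhCYGB replicate 2. By edgeR 896 genes had an unadjusted p under 0.05 with a 2-fold change. Of the 62 DESeq2 genes 58 were also called by edgeR without rhCYGB replicate 1, which called 3391 of 14647 genes. DESeq2 used those same libraries, so this overlap is no independent support. Leaving out each library in turn gave 0 to 3391 genes, 0 to 2881 with a 2-fold change, 0 to 958 transcripts and 18 to 26 lists, and each highest gene and transcript count came without rhCYGB replicate 1. Limma on log2(TPM + 1) called 1 transcript and legacy=FALSE 3, isoforms of Col4a1, Mtif2 and Golm1, which were named after their values were seen. With an estimated correlation 0 lists passed, and 0 with the length trend also removed. Removing the length trend left 25 lists past, of them 21 of the 22 in the same direction and 4 others, the activated stellate cell, neutrophil, unfolded protein and circadian clock lists. With rhCYGB replicates 2 and 3 both left out 1 rhCYGB library remains, so the values of that setting rest on 1 animal, their spread comes from the vehicle libraries alone, and its calls of genes and lists do not show stability. No paired analysis was possible because the groups hold different animals and the replicate numbers follow only the order of deposition. Of 1142 alternative values of 82 named genes, 959 kept their sign without passing, 71 passed with the same sign and 112 changed sign. None of these genes passed in the edgeR comparison. The log2 fold changes that changed sign follow. On log2(TPM + 1), where the median of all genes was -0.61, they were Cald1 -0.57, Ecm1 -0.10, Mmp14 -0.15, C1qa -0.42, C1qb -0.44, Plvap -0.51, Stab1 -0.57, Trf -0.54, Cyp3a11 -0.55, Akr1c6 -0.52, Hpx -0.43, Eno1 -0.023, Hp -0.18, Bst2 -0.27, Tef -0.28, Mcl1 -0.54, Hspa8 -0.49, Cps1 -0.16, Jund -0.38, Hba-a2 -3.25, Cela1 -0.41 and Krt19 -0.29. With rhCYGB replicates 2 and 3 both left out they were Ecm1 -0.099, Tgfbr2 0.10, Mmp14 -0.37, C1qa -0.71, C1qb -0.65, Sdc1 0.23, Plvap -0.0065, Stab1 -0.26, Trf -0.11, Akr1c6 -0.26, Cyp27a1 -0.017, Hrg -0.094, Hpx -0.47, Eno1 -0.13, Ldha 0.11, Ccl9 0.48, Cxcl12 0.10, Hp -0.65, Bst2 -0.17, Scd1 0.54, Dbp -0.069, Ccng1 0.29, Hspa8 -0.44, Jund -0.36, Hba-a2 -11.36, Cela2a -0.93 and Krt19 -0.63. With the length trend removed they were Fn1 0.062, Eng 0.15, Tgfbr2 0.10, C1qa -0.054, C1qb -0.098, Akr1c6 -0.034, Ccl9 0.0041, Bst2 -0.086, Ccng1 0.0057, Hba-a2 -0.87, Cela2a -0.013 and Cela1 -0.059. By limma-voom with quality weights they were Eng 0.24, S100a9 0.022, Cyp3a11 -0.14, Ccnd1 0.071, Fdps 0.24 and Calr 0.15. By limma-voom without weights they were Mup20 0.054, Hba-a2 -3.31 and Hbb-bs 0.48. With upper-quartile factors they were Hba-a2 -0.052. With DESeq2 size factors they were Eng 0.010 and Calr 0.036. By the DESeq2 test they were Eng 0.0014 and Calr 0.025. Over leaving out each library in turn the ranges that crossed 0 were Akr1c6 -0.086 to 0.46, Calr -0.29 to 0.23, Ccl9 -0.45 to 0.26, Ccnd1 -0.53 to 0.071, Ccng1 -0.41 to 0.075, Cd74 -1.08 to 0.23, Cela1 -0.042 to 0.52, Clu -0.33 to 0.25, Cyp3a11 -0.081 to 0.36, Eng -0.22 to 0.11, Fdps -0.25 to 0.21, Hba-a2 -0.80 to 0.79, Hbb-bs -4.63 to 5.80, Lcn2 -0.37 to 0.27, Ldha -0.43 to 0.052, Mup20 -0.72 to 0.64, Plvap -0.045 to 0.42, S100a9 -0.59 to 0.0043, Trf -0.018 to 0.41 and Vim -0.61 to 0.097. The cause was not tested except where the text says so. The effect of depth was not tested, and the replicate spread left 2-fold changes undetectable in the simulation.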

Other observations

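Tests chosen only after the result was seen are the length-trend tests of the calls and of the female-biased and PPAR-alpha lists, the slope count by treatment, and the comparisons of female-biased with male-biased genes and of PPAR-alpha targets with plasma protein genes. With 3 mice against 3 there are 10 splits, too few for a share under 0.05. By edgeR the real split gave 0 genes (highest other 3), 0 genes with a 2-fold change (highest other 3) and 0 transcripts (highest other 76). By camera with the preset correlation it gave 22 lists (highest other 26), and with an estimated correlation every split gave 0. With 0 in the real split all 10 splits give as many genes, 2-fold genes and transcripts by construction, which tests nothing. With the preset correlation 2 of the 10 splits gave as many lists. At an unadjusted p under 0.05 the real split gave 1170 genes and 3 of 10 splits gave as many, the highest being 4415 when vehicle replicates 1 and 3 and rhCYGB replicate 1 were set against the rest. That split calls several times the real number. It sets the libraries with the highest length slopes, 0.40, 0.06 and 0.24, against those with the lowest, -0.02, -0.35 and -0.33. It also sets rhCYGB replicates 2 and 3 apart from rhCYGB replicate 1. A measurement difference and a response that rhCYGB replicate 1 lacked therefore cannot be told apart by it.

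Without rhCYGB replicate 1, edgeR called 3391 genes where the 6 libraries gave 0. Removing the length trend left 90.2% as many calls, 3057, of which 2325 were shared. For the shared calls this argues against the trend on length itself as the whole cause. The removal takes out only the curve common to genes of like length. In these 5 libraries the slopes of both rhCYGB libraries lay below all vehicle slopes. Other effects of library quality therefore cannot be told apart from treatment. Over the 3391 genes rhCYGB replicate 1 had a median position of -0.071 between the vehicle mean at 0 and the mean of the other rhCYGB libraries at 1. A single wrong label, a missed dose or a weak response may each place it there and cannot be told apart. Leaving out a vehicle library called 0 genes and so gave no position to compare with. The length slope of 0.24 and TMM factor of 1.18 of rhCYGB replicate 1 also lay within the vehicle ranges. Vehicle slopes were 0.40, -0.02 and 0.06, and vehicle factors 1.45, 1.07 and 1.18. The other rhCYGB libraries had slopes of -0.35 and -0.33 and factors of 0.74 and 0.63. A measurement difference of those libraries therefore stays open as well. The real split was the 1 of 10 splits of the 5 libraries with as many calls (highest other 2), and 10 splits are too few for a share under 0.05.

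The trend with transcript length differed between libraries, from 0.40 in vehicle replicate 1 to -0.35 in rhCYGB replicate 2. Within 188 genes with a pair of isoforms differing at least 2-fold in length, the median ratio of the longer to the shorter isoform followed the slopes over the 6 libraries, with Spearman's rho of 1 (exact permutation p = 0.00278) and Pearson's r of 0.993 (exact permutation p = 0.00139). Without the 2 libraries farthest from the median slope r was 0.995. A length-dependent measurement effect such as RNA integrity is consistent with this, as a hypothesis. Whether treatment adds to it cannot be told apart, since 1 rhCYGB library had a slope above the middle vehicle library and the other 2 lay below all vehicle libraries.

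Female-biased and PPAR-alpha target genes had higher values with rhCYGB. If more hepatocyte RNA were the whole cause of the female-biased part, male-biased hepatocyte genes would be higher by about as much, but the median log2 fold changes were 1.37 and -0.29, the latter over 9 higher and 11 lower genes, a difference of 1.66 (permutation p = 0.00137 over genes, which are not independent replicates). By library the female-biased medians were -0.48, -0.46 and -0.21 with vehicle and 0.049, 1.13 and 0.50 with rhCYGB. The male-biased ones were -0.92, 0.57 and 0.045 with vehicle and 0.32, -0.32 and 0.040 with rhCYGB. The female-biased median exceeded the male-biased one in vehicle replicate 1 and rhCYGB replicates 2 and 3 only. The difference thus did not part the groups by mouse and cannot decide on hepatocyte RNA. For the PPAR-alpha targets more hepatocyte RNA stays open as well. Their median of 0.60 was not above the 0.80 of plasma protein genes (difference -0.21, permutation p = 0.424). The medians were 1.26 and 0.47 with the length trend removed, which argues against that trend as the whole cause. Other differences in library quality would stay after that removal and were not tested. Feeding state may contribute and stays open, since 12 fasting-induced genes in no other list had a median of 0.52, at the 94.1 percentile of 10000 random lists matched on expression, below the bound set in advance. Treatment stays open too, and these list members did not pass by edgeR when adjusted over all genes, while DESeq2 called some of them, Cyp4a10, Cyp4a14 and Angptl4 included.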
